A study of Mus musculus with 4 samples.

How the data were processed

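The series holds 4 libraries of mouse striatum: 1 input and 3 immunoprecipitated (IP) fractions, sequenced on the Ion Proton platform per the labels' protocols. The title names a GS-tagged TRα1, the thyroid hormone receptor alpha 1, in animals carrying Gad2-Cre and a Thra-GS allele. Per the labels, the IP was done on IgG-coated magnetic beads, which hold the tag. Per the labels' protocols, nuclei were sonicated and the lysates cleared before the IP. Samples were grouped as input or IP from the labels, and the design text sets the IP fractions against the input.

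One peak list for the whole series was analysed. Bowtie2 2.3.4.2 and MACS2 2.1.1.20160309.0 and the builds GRCm38 and mm10 are named in the submitters' processing notes, without the role or settings of either tool. Peak names begin with MACS2, per the file headers and values. Whether peaks were called on pooled IP fractions or on 1 of them is not given in the sources used here. The deposited list gives each peak's start, end, width and summit, per the file headers. The authors deposited for each peak the pileup signal at the summit, which is the height of stacked fragments after the caller's scaling. The authors' fold enrichment is a linear ratio of that pileup to the local background, with 1 added to both. The authors' p-value and q-value columns hold −log10 of each value, per the file headers and the range of the numbers. These scores are the authors' own and were used here to describe, rank and filter peaks within the list.

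The file was checked before use. Peak width was equal to end minus start plus 1 in 100% of peaks. Names are numbered up to 7653, and 169 of those numbers are not among the 7484 peaks used here. Pileups lay on a grid of step 0.939 with a largest residual of 0.00574, so 1 scale factor had been applied to the IP. In steps of that grid, summits held 10 to 305 fragments with a median of 23. The background at each summit was recovered as (pileup + 1) / fold − 1. A Poisson p computed from pileup and background lay within 0.01 of the deposited −log10 p for 99.9% of 7483 peaks. Read totals per library were not used here, and no value per library enters any test, so no replicate error can be given. Intervals and tests over peaks or genes cover counting error within this 1 list, and reads amplified by PCR are not independent molecules.

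Genes came from a RefSeq table of assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes and 49943 genes of any type on chromosomes 1 to 19, X and Y. The table gives gene starts and ends but no strand, exons or sequence. Either annotated end of a gene therefore stood in for the transcription start site, and the span from the first to the last annotated gene stood in for the length of a chromosome. No genome sequence was used here, so the intended tests of DR4 elements, half-site spacing, other motifs and repeat overlap, and the shares in exons and introns, are not reported.

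The tests, the 18 gene lists and the rule for naming genes were fixed before the data were examined. Summits within 1 kb of a protein-coding gene end were counted against 1000 sets of random positions with the same number per chromosome, in a two-sided permutation test. A gene counted as having a peak when a summit lay within 30 kb of either of its ends. Each list was set against all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 18 lists. All list symbols matched the table. The lists covered thyroid hormone targets in brain and outside it, the receptor with its coregulators and hormone supply, GABA synthesis and receptors, interneuron identity, striatal projection neurons, perineuronal net, axon guidance, voltage-gated channels, the circadian clock, Krueppel-like and immediate early factors, and Wnt and Hedgehog signalling. Further lists held markers of glutamatergic neurons, astrocytes, oligodendrocytes, microglia and vessels, and muscle and liver genes as a control. Named genes are those nearest to the 25 strongest peaks within 30 kb of a gene end, up to 4 members with the strongest peak per list, and Thra, Thrb, Gad2, Klf9, Hr and Dio3. Other genes named were chosen after their values were seen. Proportions carry 95% exact (Clopper-Pearson) intervals, and peak densities 95% exact Poisson intervals.

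Alternatives fixed in advance were a −log10 q of at least 10, the peaks above the median fold, removal of the 1% highest pileups and 1% widest peaks, gene-end distances of 500 bp and 2 kb, ends of all annotated genes, windows of 5 kb and 100 kb, the gene span with 5 kb on both sides, 10000 random lists matched on gene length and number of transcripts, and 1000 random sets of positions. Alternatives chosen after seeing the data left out 27 peaks whose background was over 4 times the lowest, left out receptor families and predicted genes, compared each list with the other lists only, or kept 1 member per locus. Counts per chromosome were fixed in advance without a test. The comparison of fold near and far from gene ends and the test of chromosome X against the autosomes were chosen after seeing the data.

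The list test and the counting at gene ends were tried on simulated data. For the gene lists, peaks were planted at 60% of the members of a simulated list of 40 genes, by moving some of the random positions. This list was called in 20 of 20 runs over 21887 genes. On the same draws with nothing planted, 0% of the lists were called. The random positions were uniform, without the gathering at gene ends or in groups seen in the data, and they reached fewer genes than the peaks did. These runs therefore do not give the power or the false-call rate on the data themselves. For gene ends, 7484 positions with 20% planted gave 22.5% recovered where 22.5% was put in, chance positions included. All planted positions lay within the 1 kb counted, so this checks the counting only. The permutation test was not run on these positions. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.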

Results

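Chromatin from mouse striatum was immunoprecipitated for GS-tagged TRα1, the alpha 1 thyroid hormone receptor, in animals with Gad2-Cre, a driver line for GABAergic neurons. The series has 3 IP fractions and 1 input, compared as 1 list of 7484 enriched regions, so no spread between fractions can be given. Regions were 174 to 1403 bp wide with a median of 260 bp, and they covered 2146 kb of the GRCm38 build. The fold enrichment over background had a median of 6.91 with quartiles of 5.55 and 9.73, and a range of 1.38 to 91.04. A fold of at least 10 was reached by 1792 peaks and a fold of at least 20 by 266.

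The comparison of IP with input asks where in the genome the IP of the tagged receptor enriched chromatin. An IP without the tag was not analysed here. Binding of the receptor was therefore not separated from unspecific recovery of chromatin by the beads, for any of the peaks below. The strongest region, on chromosome 17 at 4626072 to 4626693, had a fold of 91.04 and a pileup of 262 over a background of 1.89. It lay inside the long non-coding RNA gene Gm34259, 368 kb from Arid1b, the nearest protein-coding gene. Among regions within 30 kb of a protein-coding gene end, the strongest was 12778 bp from Wnt10a, which encodes a secreted Wnt ligand. That peak had a fold of 51.9 at chromosome 1, 74816506 to 74817126, and its summit was also 137 bp from the tRNA gene n-TGgcc3. Next came a fold of 47.8 at 1479 bp from Eef2, the translation elongation factor 2 gene, and 45.9 inside Wipi1, an autophagy gene. A fold of 43.9 lay 20756 bp from Cipc, which encodes a CLOCK-interacting protein, and 17008 bp from the non-coding gene Gm32934.

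Others of the top 25 gene-linked peaks, named by rank and not by function, lay at the following genes. Nr1d2, which encodes the clock repressor REV-ERBβ, had a peak of 39.6 inside its span, 763 bp from one end. Rgs9, a regulator of G-protein signalling known from the striatum, had 4 peaks with a highest fold of 36.1. The potassium channel gene Kcnq3, of the M-current family, had a peak of 35.4 inside its span. Slc24a2, a sodium, calcium and potassium exchanger gene, had 41.3 at 24770 bp, and Chn1, a Rac GTPase-activating protein gene, had 39.4 at 287 bp. A fold of 38.1 lay 2221 bp outside Upf1, the RNA decay helicase gene, and inside the span of Gdf1, a growth factor gene. The splicing kinase gene Clk3 had a fold of 34.2. Rcn1, which encodes a calcium-binding protein of the endoplasmic reticulum, had 43.6, and Ppp1r32, named as a phosphatase 1 subunit gene, had 42.9. Flywch2 had 42.0 at 136 bp inside the gene, and Uck1, a pyrimidine nucleoside kinase gene, had 36.2. Mllt3, a chromatin reader gene of transcription elongation, had 35.5, and Hnrnpul1, an RNA-binding protein gene, had 34.9. Def6, a guanine nucleotide exchange factor gene, had 35.8, and Epb41l2, of the membrane cytoskeleton, had 35.1. Qrsl1, a mitochondrial translation gene, had 37.1, and Wfikkn1, which encodes a secreted protease-inhibitor-like protein, had 36.6.

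Klf9, a Krueppel-like factor gene induced by thyroid hormone, had 4 peaks, all on the lower-coordinate side of the gene. The strongest, at chromosome 19, 23135794 to 23136233, was 5181 bp from the gene with a fold of 32.9, and its neighbours had folds of 15.8, 7.52 and 6.20. Hr, which encodes the corepressor hairless, had 3 peaks with folds of 34.2, 9.41 and 7.50. The peak of 34.2, at chromosome 14, 70549300 to 70549788, was 4589 bp from Hr and 532 bp from Reep4. Thra, the gene of the tagged receptor, had 4 peaks within 30 kb, with folds of 14.4 inside the gene and 12.2, 10.4 and 9.78 beyond its upper end. The peaks of 10.4 and 9.78 lay in the span of the neighbouring clock gene Nr1d1. Thrb, the second receptor gene, had a peak of 12.5 at 26126 bp and a peak of 4.90 inside the gene.

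Dio3, which encodes the deiodinase that inactivates thyroid hormone, had peaks of 11.6 at 9163 bp and 8.94 at 27906 bp. A wider view, chosen after its values were seen, held a fold of 39.4 at 51.3 kb and a fold of 54.0 at 92.4 kb from Dio3. The latter, at chromosome 12, 110373233 to 110373733, was the second-ranked peak of the list and lay nearer to Ppp2r5c, a phosphatase 2A subunit gene, at 73.6 kb. Gad2, the GABA-synthesising enzyme gene that carries the Cre driver, had 1 peak, inside the gene at chromosome 2, 22622248 to 22622629, with a fold of 18.8. Both Gad2 and Thra carry engineered alleles per the title, and reads from these alleles were not separated here.

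**Figure D1:**
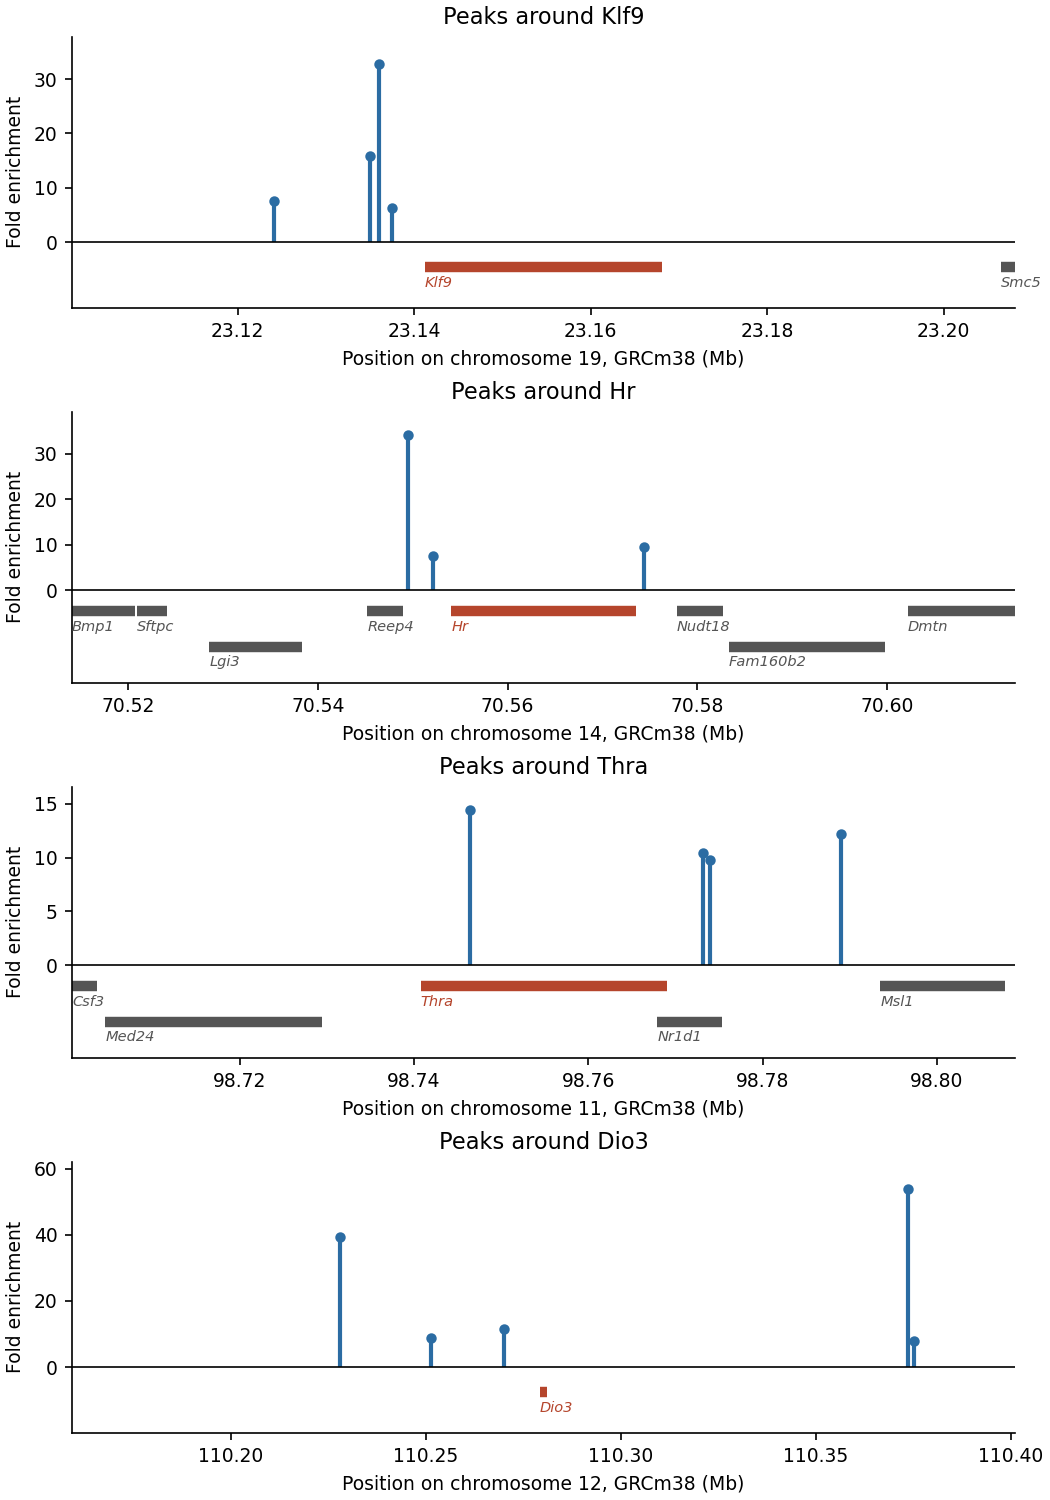
Peaks around Klf9, Hr, Thra and Dio3, drawn as vertical lines at each summit with the authors' fold enrichment on the y axis and the GRCm38 position in Mb on the x axis; bars below 0 are protein-coding gene spans, the named gene in red. The Klf9 peaks, up to 32.9, all lie left of the gene, and the peaks of 39.4 and 54.0 flank Dio3 at 51.3 and 92.4 kb, the latter 73.6 kb from Ppp2r5c.

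Peaks gathered at the ends of protein-coding genes and inside them. Within 1 kb of a gene end lay 1291 summits, 17.3% (95% exact interval 16.4 to 18.1), against 3.15% ± 0.209 (SD) of random positions, a ratio of 5.47. From 1 to 5 kb the share was 13.9% against 9.80%, and inside gene spans it was 59.5% against 40.6%. Regions more than 100 kb from any gene end held 18.7% of the summits, against 35.9% of random positions. Each of these 4 differences had a two-sided permutation p of 0.002, the smallest that 1000 random sets can give. From 5 to 30 kb the share of 28.2% did not differ from the random 27.9% (permutation p = 0.531), and from 30 to 100 kb it was 21.8% against 23.2% (permutation p = 0.002). Examples at gene ends were Gabra4 at 7 bp with a fold of 18.2, Kcna5 at 9 bp with 24.4, Rxrb at 84 bp with 29.0 and Uck1 at 49 bp with 36.2. Which end is the transcription start was not used here, so the counts join both ends of a gene.

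Peaks at gene ends and distant ones did not differ in median fold by this test. The median fold was 7.06 within 1 kb and 6.85 beyond 100 kb, a difference of 0.210 (permutation p = 0.230). With only the 3986 peaks of −log10 q of at least 10, the difference was 0.507 (permutation p = 0.0364), and in pileup it turned to −0.94. A fold of at least 20 was reached by 4.65% of the peaks within 1 kb and 2.71% of those beyond 100 kb. Of the 100 strongest peaks, 25 lay within 1 kb of a gene end and 12 beyond 100 kb, where all peaks had 17.3% and 18.7%. These shares among strong peaks were not tested.

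**Figure D2:**
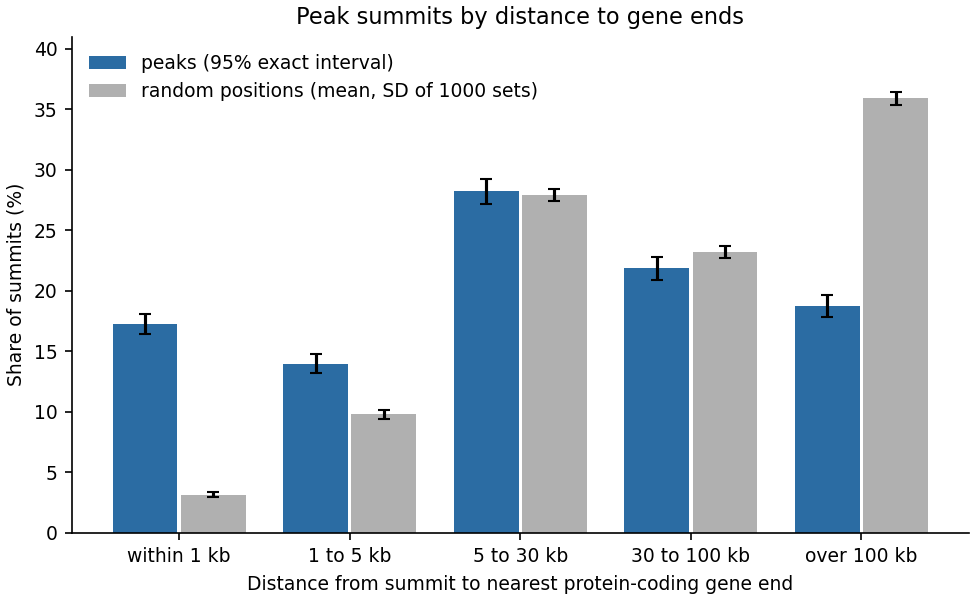
Share of the 7484 summits (blue, percent, 95% exact intervals) and of random positions (grey, mean with SD over 1000 sets) by distance to the nearest protein-coding gene end. Peaks exceed random positions within 1 kb (17.3% against 3.15%) and fall short beyond 100 kb (18.7% against 35.9%).

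A peak within 30 kb of an end was found for 6593 of 21887 protein-coding genes, 30.1%, against 4813 ± 81.6 (SD) genes for random positions (permutation p = 0.002). The 18 gene lists ask whether particular functions were over-represented among these genes, and 4 lists were. Circadian clock genes stood highest, with peaks at 18 of 24 members, 75% (exact interval 53.3 to 90.2), against 30.1% of other genes, with an adjusted p of 0.000134 by Fisher's exact test. Besides Nr1d2 they included Klf9, Dbp at 30.4, a PAR bZIP output factor gene, and Bhlhe41 at 18.2, a transcriptional repressor gene. Npas2 had 6 peaks, Cry2 5 and Per1 4, while Clock, Per2, Cry1 and Bhlhe40 were among the members without a peak.

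Striatal projection neuron genes had peaks at 22 of 34 members, 64.7% (exact interval 46.5 to 80.3), with an adjusted p of 3.35e-04 by Fisher's exact test. The dopamine receptor gene Drd2 had a peak of 19.2 at 588 bp from the gene, and Drd1 had 3 peaks of up to 6.79. Rasgrp2, a guanine nucleotide exchange factor gene, had 19.1, and Bcl11b, a transcription factor gene of projection neurons, had 5 peaks of up to 17.2. Gng7, the G-protein gamma subunit gene, had 10 peaks, and Ppp1r1b, which encodes DARPP-32, had 6. Adora2a, Penk, Pdyn, Tac1, Pde10a and Foxp2 were among the members without a peak.

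Voltage-gated potassium and sodium channel genes had peaks at 22 of 37 members, 59.5% (exact interval 42.1 to 75.2), with an adjusted p of 0.00138 by Fisher's exact test. Kcnq3 led with 35.4, followed by Kcna5 at 24.4, Kcnh2 at 21.5 and Kcnd3 at 20.8. Scn2b and Scn4b share their strongest peak of 10.7. With 1 member per locus, an alternative chosen after seeing the data, 19 of 34 channel genes had a peak (adjusted exact p = 0.0129).

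Thyroid hormone targets in brain had peaks at 20 of 40 members (exact interval 33.8% to 66.2%), with an adjusted p of 0.0403 by Fisher's exact test. Flywch2 at 42.0, Hr at 34.2, Klf9 at 32.9 and Dbp at 30.4 had the strongest, and Nrgn, the neurogranin gene, had 4 peaks of up to 17.4. Bdnf, Reln, Mbp and Shh had none. This call held in 7 of 12 alternatives, with adjusted exact or permutation p from 0.000200 to 0.239, and was lost against random lists matched on gene length and transcripts (adjusted permutation p = 0.134). Of the alternatives where it held, keeping 1 member per locus dropped no member and so repeated the main test. Leaving out peaks of high background also kept 20 of 40, and random positions were exceeded by protein-coding genes as a whole. Klf9, Dbp and Rora belong to both this list and the clock list, and 13 of the 40 members are also in another list.

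GABA synthesis, transport and receptor genes had peaks at 12 of 21 members, 57.1% (exact interval 34.0 to 78.2), with an adjusted p of 0.0519 by Fisher's exact test. Members with the strongest peaks were Gad2 at 18.8, Gabra5 and Gabrg3, which share a peak of 23.1, and Gabra4 at 18.2, shared with Gabrb1. Krueppel-like and immediate early factor genes reached 15 of 30 members (adjusted exact p = 0.0794), with Egr4 at 16.6, Klf13 at 14.3 and Egr2 at 13.7. Receptor, coregulator and hormone supply genes reached 10 of 21 (adjusted exact p = 0.215), led by Hr and by Rxrb, the retinoid X receptor beta gene, at 29.0. These 3 lists passed when the window was 5 kb or the gene span, with ratios of 2.09 to 2.99, and the number of lists passing was then 7 and 8. The gene span gives longer genes a wider window, and gene length was not matched in that setting.

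Interneuron identity genes had peaks at 6 of 31 members, 19.4% (adjusted exact p = 0.434), with Pvalb, the parvalbumin gene, at 9.77, Kcnc1 at 6.52, Sp9 at 5.55 and Satb1 at 5.41. Sst, Npy, Vip, Lhx6 and Chat had no peak. With a −log10 q of at least 10, and also above the median fold, 1 of 31 interneuron genes kept a peak, with ratios of 0.173 and 0.182 in place of 0.642 (adjusted exact p = 0.0746 and 0.0824). Hormone targets outside brain reached 8 of 22 (adjusted exact p = 0.644), with peaks at Gh of 16.6, Hcn2 of 10.4, Pck1 of 8.70 and Atp2a2 of 6.20. Wnt and Hedgehog genes reached 11 of 39 (adjusted exact p = 0.914), with Gli3 at 11.3, Axin2 at 11.1 and Lrp5 at 9.41 after Wnt10a. Axon guidance genes reached 10 of 42 (adjusted exact p = 0.644), with Robo3 at 32.2, Ntng2 at 18.2, Epha3 at 16.9 and Dcc at 14.97. Over the gene span with 5 kb on both sides, the axon guidance ratio turned from 0.790 to 2.25 (adjusted exact p = 0.00146). Longer genes have a wider window in that setting, and gene length was not matched there. In the 30 kb window, lists matched on gene length and transcripts gave axon guidance 0.707 (adjusted permutation p = 0.406). Perineuronal net and matrix genes reached 6 of 25 (adjusted exact p = 0.747), with Mmp9 at 13.3, Tnr at 6.82, and Ncan and Hapln4 sharing a peak of 7.93.

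Markers of other cell types of the striatum or of cortex did not exceed other genes. Glutamatergic neuron markers had peaks at 4 of 19 members (adjusted exact p = 0.644), Neurod2 at 10.1, Camk2a at 8.15, Cux2 at 7.50 and Rorb at 5.87, the Neurod2 peak shared with Ppp1r1b. Astrocyte markers reached 4 of 18 (adjusted exact p = 0.733), with Gli3 at 11.3, S100b at 10.7, Slc4a4 at 8.47 and Slc7a10 at 7.50. Oligodendrocyte markers reached 6 of 20 (adjusted exact p = 1), with Mobp at 11.4, Fa2h at 8.80, Myrf at 8.23 and Opalin at 5.50. Microglia markers reached 2 of 18 (adjusted exact p = 0.239), Trem2 at 10.4 and P2ry12 at 5.47. Endothelial and mural markers reached 4 of 20 (adjusted exact p = 0.644), with Esam at 17.4, a peak shared with Nrgn, Emcn at 11.2, Flt1 at 5.48 and Abcb1a at 5.03. Muscle and liver control genes reached 4 of 27, 14.8% (adjusted exact p = 0.215), with Des at 14.4, Cyp2e1 at 7.50, Acta1 at 6.35 and Apoa1 at 6.20. The summits given for Gh, Slc7a10, Myrf, Opalin, Trem2, P2ry12, Abcb1a, Cyp2e1 and Apoa1 lay inside the span of another protein-coding gene. Expression levels of the listed genes in the striatum were not used here, and no list was tested against another single list.

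**Figure D3:**
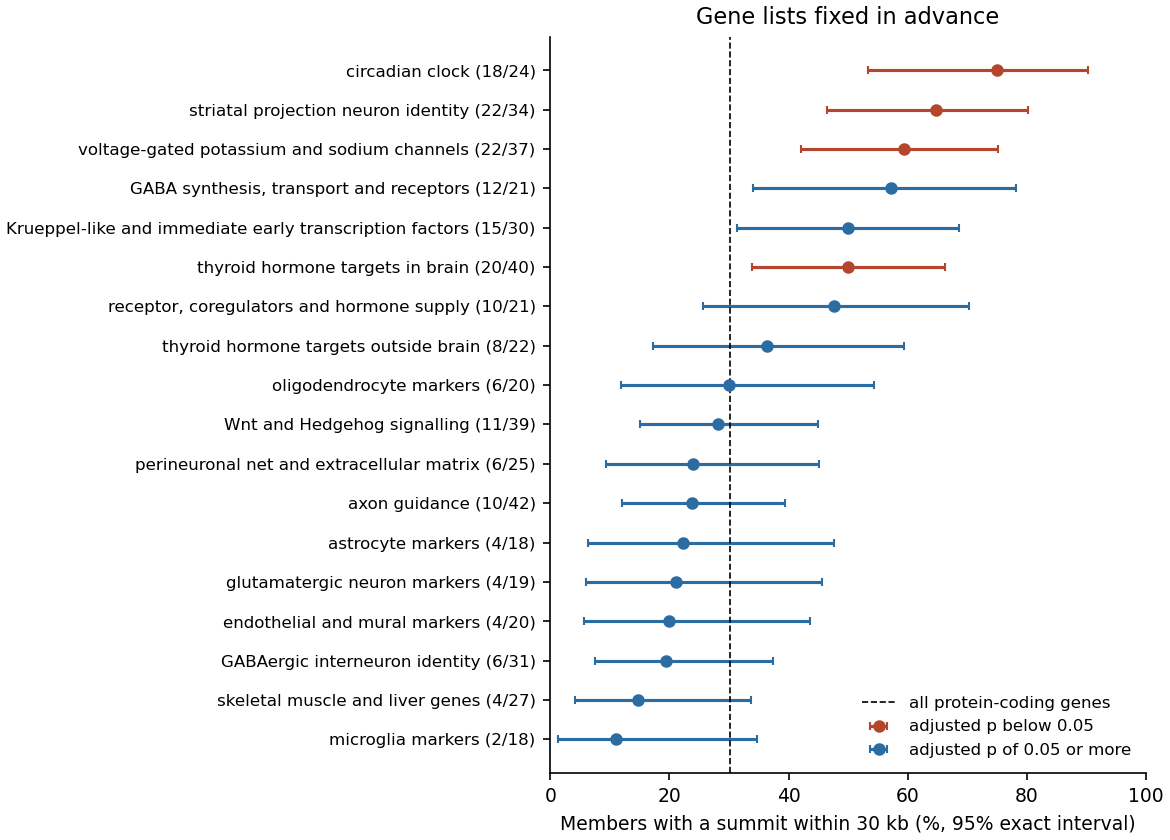
Share of the members of each of the 18 lists with a summit within 30 kb of a gene end (percent, x axis, points with 95% exact intervals), with the number of members with a peak over the list size. Red points have an adjusted p below 0.05, and the dashed line is the 30.1% of all protein-coding genes; the clock (75%) and striatal projection neuron (64.7%) lists stand highest.

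By chromosome, peaks were densest on chromosome 11, with 4.31 per Mb, and chromosome 9, with 3.88 per Mb. The autosomes together held 7412 peaks, 3.04 per Mb. Chromosome X held 69 peaks, 0.404 per Mb (exact Poisson interval 0.315 to 0.512), which is 0.133 of the autosomal density (0.103 to 0.169, exact binomial p = 1.15e-130). Per 100 protein-coding genes there were 7.14 peaks on X and 35.9 on the autosomes. Among peaks with a fold of at least 10 these numbers were 1.55 on X and 8.59 on the autosomes. Chromosome Y held 3 peaks, between 90771174 and 90798385. The count on chromosome 9 includes 12 peaks at its start, 3007940 to 3037522, with folds of 1.38 to 1.81 over a median background of 153.

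**Figure D4:**
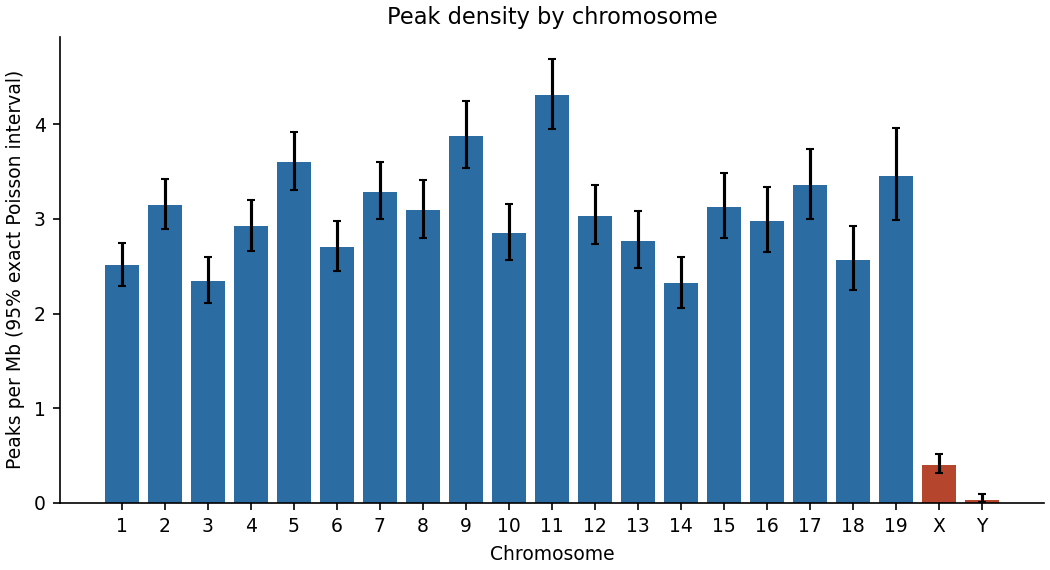
Peaks per Mb of annotated span for each chromosome (bars from 0, with 95% exact Poisson intervals; X and Y in red). The lowest autosome, chromosome 14, has 2.32 per Mb, and X has 0.404.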

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

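The alternatives for fold near gene ends and for chromosome X, and those without receptor families, against other lists or with 1 member per locus, were chosen after the results were seen. Of all comparisons with an alternative, 217 were kept, which for counts means within 1.5 times, and 9 counts moved by more. For ratios and differences, kept means the same direction and passing or not passing as before, whatever the size of the change. Lists that passed in neither setting are thus counted as kept, such as interneuron genes at 0.642 and, with a −log10 q of at least 10, 0.173. Direction turned in 19, including axon guidance over the gene span, which also passed. Of the rest, 8 passed anew and 5 no longer passed. The gene-end ratio stayed between 3.47 and 7.64 and the X ratio between 0.130 and 0.140. Clock, striatal projection neuron and channel lists passed in 12 of 12 alternatives. For the clock and striatal lists, keeping 1 member per locus dropped no member and so repeated the main test.

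With a −log10 q of at least 10, 3986 peaks were left, the fold difference near gene ends passed at 0.507, and the ratios turned to 0.977 for hormone targets outside brain, 1.02 for axon guidance and 1.19 for astrocytes. Above the median fold, 3714 peaks were left and these ratios were 0.768, 1.07 and 1.252. Without the 1% extremes, hormone targets in brain no longer passed (1.51) and oligodendrocytes turned to 1.01. The window of 5 kb gave 7 passing lists, with receptor and coregulators at 2.71, GABA at 2.71 and Krueppel-like factors at 2.71, and axon guidance turned to 1.16 and Wnt to 1.04. The window of 100 kb took hormone targets in brain to 1.26 and Wnt to 1.10. The gene span, where longer genes have a wider window, gave 8 passing lists, with receptor 2.24, GABA 2.99 and Krueppel-like factors 2.09. It turned axon guidance to 2.25, hormone targets outside brain to 0.712, perineuronal net to 1.05 and Wnt to 1.21. Random positions gave Krueppel-like factors 2.49, perineuronal net 1.03, Wnt 1.11 and oligodendrocytes 1.30. Protein-coding genes as a whole also exceeded random positions, with 6593 genes against 4813. A ratio above 1 in this setting therefore does not place a list above other genes. Hormone targets in brain did not pass against matched lists (1.51), without receptor families (1.48) or against other lists (1.43). With 1 member per locus oligodendrocytes turned to 1.05, and with pileup the difference near gene ends turned to −0.94. Peak numbers moved by construction, ratios to random positions have another baseline, and the cause of the other changes was not tested.

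The sets without repeats and all motif alternatives were not run. No paired analysis was possible because the list has no value per library, and leaving out a fraction was not possible.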

Other observations

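The counts by gene family, the tests of chromosome X other than that on all its peaks at halved reads, and the test at the start of chromosome 9 were chosen after the results were seen. Genes were grouped by the letters that open their symbols into 165 families of at least 15 genes, of which 8 had peaks more often than other genes and 22 less often (Fisher's exact test, adjusted over the families). F-box genes with leucine-rich repeats, the Fbxl substrate receptors of ubiquitin ligases, had peaks at 13 of 18 members (adjusted exact p = 0.0033), with Fbxl21 at 16.6. Protein phosphatase genes had peaks at 38 of 77 members (adjusted exact p = 0.00465), among them the catalytic subunit genes Ppp1ca at 26.3 and Ppp3ca, of calcineurin, at 22.5. TBC genes, Rab GTPase-activating proteins, reached 18 of 30 (adjusted exact p = 0.00826), and the myosin genes 14 of 25 (adjusted exact p = 0.0455). Zbtb factors reached 21 of 41 (adjusted exact p = 0.0342), with Zbtb7a sharing the peak of 47.8 beside Eef2. Olfactory receptor genes had peaks at 47 of 1110 members, 4.23% (adjusted exact p = 4.45e-109), vomeronasal receptor genes at 7 of 355 and cytochrome P450 genes at 14 of 99. Neighbouring members share peaks and lack them together, so these p-values are too small.

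Peaks also lay in groups. Of the 7484 summits, 1438 (19.2%) had another summit within 10 kb, against 5.97% ± 0.357 (SD) of random positions and at most 6.97% in 100 sets. The random positions were uniform along each chromosome, so grouping was not separated from the gathering of peaks at gene ends and inside genes. Gng7 and its neighbour Diras1 had 10 and 7 peaks, with the same highest fold of 15.6, so their counts can hold the same peaks. The acid-sensing channel gene Asic1 and the synaptic scaffold gene Baiap2 had 7 each. Predicted genes ranked as high, with 10 peaks at Gm40363 and 8 at Gm36327, which share a highest fold of 13.3. Strong peaks over 30 kb from any gene end lay inside Spata13 and Sik3 (both 40.98) and inside the sodium-calcium exchanger gene Slc8a3 (36.4). A fold of 53.7 on chromosome 5, 28859707 to 28860277, was 333 kb from Rnf32 and 1605 bp from the non-coding gene Gm42243.

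Chromosome X had fewer peaks than its length or genes would give, with 0.199 (0.155 to 0.252) of the autosomal peaks per gene, so fewer genes are not the whole cause. At halved reads, 69.0% ± 0.410 (SD, 100 draws) of autosomal peaks kept the lowest −log10 p of the list, or 46.1% after the lower gene density, where X had at most 16.9%, but called peaks thin out below their most frequent height of 19 fragments, so this comparison does not decide. At a fold of 5 to 10 the ratio per gene was 0.434 (0.312 to 0.589), below the 0.634 of the lowest autosome, which goes against a single copy with fewer genes but reaches into the same heights where peaks thin out. At 19 fragments or more, X had 0.455 (0.336 to 0.603) of the autosomal peaks per Mb at halved reads, below the 0.715 of the lowest autosome, which argues against a single copy alone. Per gene the ratio was 0.681 (0.503 to 0.902). This interval lies below 1, but the lowest autosome had 0.610, so the comparison per gene does not decide. For a fold of at least 10, fold on autosomes was recomputed from halved pileup over a background kept at or above its lowest value. The ratio per gene was then 0.796 (0.442 to 1.33), on 15 X peaks. A single copy with fewer genes may therefore be enough for peaks of that fold, and it stays open for the others. The sex of the animals is not given in the labels, autosomal peaks need not have the strengths of those on X, mappability and the authors' filtering stay open, and no biological explanation was tested.

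Transfer RNA genes had peaks more often than protein-coding genes. A summit lay within 1 kb of 67 of 408 tRNA genes, 16.4% (exact interval 13.0 to 20.4), against 6.63% of protein-coding genes (Fisher's exact test, p = 2.30e-11), and the 43 peaks concerned had a median fold of 5.74. Protein-coding ends beside them do not account for this, since 11.7% of the 300 tRNA genes over 5 kb from such an end had a summit against 0.492% of random positions held to that distance, nor does counting clustered genes more than once, with 20.5% (14.8 to 27.2) of 176 joined loci. The background at these summits was 1.04 times that of other peaks, which argues against stacked reads of repeated copies. Binding of the receptor there and unspecific recovery of highly transcribed chromatin by the beads both stay open as hypotheses, since an IP without the tag was not analysed here; ribosomal protein genes, tested for the latter, had 10.8% against 6.61% (Fisher's exact test, p = 0.121).

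At the start of chromosome 9, 12 peaks between 3007940 and 3037522 had a median pileup of 247 and a median fold of 1.60. Their median background was 76.5 times that of other peaks, which is consistent with reads of repeated sequence stacked on few reference copies. The reference sequence was not used here, so the repeat itself was not examined, and no biological explanation was tested.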
